A study of Mus musculus with 12 samples.

How the data were processed

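Poly(A) RNA was sequenced from 12 libraries of sorted mouse cells, 3 each of the Progenitor, Intermediate, SMC1 and SMC2 populations. Per the labels' protocols, aortas with their perivascular fat were minced and digested with collagenase and dispase, cells were sorted into a serum buffer, and RNA was purified from Trizol lysates. Libraries came from a SMART-Seq kit for very low input, which amplifies full-length cDNA and does not mark strand, so reads from a gene and an antisense partner cannot be told apart. The antibodies and gates of the sort were not given in the sources used here, so a gene used for sorting cannot be told from a gene found by the comparison. The labels number the libraries 1 to 3 in each group without saying whether a number marks an animal; p-values therefore measure the spread between these libraries, which may be technical in part.

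The authors deposited 3 tables over 33352 genes with Ensembl identifiers. The first holds raw read counts, deposited as whole numbers per gene and library. The second holds normalized counts, a signal that the authors made by dividing each library's counts by a size factor; DESeq2 size factors recomputed from the counts differed from the deposited ones by at most 5.12e-11. The third holds regularized log2 values made by the authors, which lay within 0.008 log2 units of the log2 normalized counts in the median of abundant genes of each library. The submitters' processing notes name STAR 2.5.2a, DESeq2 1.26.0 and the build mm10. The program that counted reads and its annotation release were not given in the sources used here. Symbols came from the deposited table. The 12078 rows without one and the 26 rows whose symbol had become a date took the name of their identifier in GENCODE M21 (GRCm38), which matched 33323 rows, and 29 rows kept no symbol. Coordinates and exon overlaps come from the same annotation.

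The raw counts were tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3). Genes passing filterByExpr (19016) entered a model with a mean per group over all 12 libraries, so that the groups shared an estimate of spread with 8 residual degrees of freedom. TMM factors scaled the libraries, dispersions were estimated robustly (common biological coefficient of variation 0.206), and differences were tested with the two-sided quasi-likelihood F test with Benjamini-Hochberg adjustment at 0.05. The standard error of a log2 change is its size divided by the square root of F. CPM values use TMM-scaled library sizes, and log2 CPM a prior count of 2. Of 6 comparisons, 3 were fixed as main and 3 as secondary. A set of 29 gene lists with 571 genes was fixed from textbook knowledge and tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Members were counted by the adjusted p over all genes and adjusted over the list alone.

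Named genes were chosen by a rule fixed before the data were examined. For main comparisons they are the 10 highest and 10 lowest log2 changes among called genes with no overlap between groups and a mean of at least 4 log2 CPM in the higher group, passing over unnamed gene models. Secondary comparisons use 4 each way. Described lists add up to 4 members with the smallest adjusted p, and 15 identity genes are given throughout. Some genes that the rule names are not reported here. The comparisons, tests, lists and most alternatives were fixed at the same time.

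Depth was 13258631 to 22647175 counts per library. The 10 most abundant genes took 15.6 ± 0.732% of counts in Progenitor, 14.3 ± 0.406% in Intermediate, 8.07 ± 0.483% in SMC1 and 7.23 ± 0.428% in SMC2 (SD, n = 3). Counts of amplified fragments are not independent molecules. No libraries of a group agreed within sampling noise, since the chi-square per degree of freedom between replicates was at least 8.17. Simulated counts with 200 changed genes, made from the Progenitor means and the real library sizes, tested the code. In the simulated comparison Intermediate minus Progenitor over 17973 genes, edgeR recovered 69% of 2-fold and 93% of 4-fold changes, and 9.5% of its calls were false. For SMC2 minus SMC1 (17891 genes) it recovered 66% and 91% with 6.5% false, and for SMC1 minus Progenitor (17997 genes) 68% and 96% with 5.7% false. In the same order, 15.6%, 14.6% and 16.3% of the calls of the DESeq2 test were false. These shares belong to 200 changed genes and do not carry over to the real comparisons, where far more genes were called. An Intermediate group simulated at 0.3 on the Progenitor to SMC1 axis was placed at 0.312. That simulation put every gene on the line, so it did not test libraries that lie off it.

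Pairing by replicate number was checked by correlating the deviations of same-numbered libraries from their group means across genes. For Intermediate and Progenitor the correlations were 0.17, 0.19 and 0.17, all above 0.1, so the numbers were taken to pair those libraries. The reported counts, errors and p-values still come from the planned fit without a block, which leaves that pairing out. A fit with the number as a block is given where it changed a call. In the other comparisons at least 1 correlation was at or below 0.1, a cut that does not exclude pairing there. Of all 12 libraries, 11 matched best with a library of their own number in another group, which goes with pairing across the populations. The fit without a block leaves any such pairing out in every comparison. The labels give same-numbered libraries of all populations a shared tag. Alternatives were DESeq2 median-of-ratios factors, upper-quartile factors, no filter, a filter of 5 CPM in 3 libraries, a DESeq2 1.42.0 Wald test, a fit of the 6 libraries compared, the replicate block, a 2-fold minimum and leaving out each library. The position of a library on an axis is the least-squares slope through 0 of its difference from the Progenitor mean on the SMC1 difference in log2 CPM, with Progenitor and SMC1 libraries left out of their own means. Figures were drawn with matplotlib 3.10.9.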

Results

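The series measured poly(A) RNA in 4 cell populations sorted by flow cytometry from the aorta and the surrounding perivascular fat of adult male CD-1 wild-type mice, aged 13 weeks. CD-1 is an outbred mouse strain, and perivascular fat is the adipose tissue around the vessel wall. The populations, named in the labels as progenitor cells (Progenitor), intermediate cells (Intermediate) and 2 smooth muscle cell populations (SMC1 and SMC2), had 3 libraries each, 12 in all. Total counts ran from 13258631 in SMC2 replicate 3 to 22647175 in Progenitor replicate 1. The title of the series names the lineage of thermogenic perivascular fat as its subject, and the comparisons ask how the sorted populations differ. Levels are CPM, counts scaled to library size, with SD over n = 3 libraries, changes are log2 with their standard error, and a gene was called at an adjusted p below 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

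The fibroblast markers Pdgfra and Cd34 separated Progenitor and Intermediate from both SMC populations, and the smooth muscle genes Acta2 and Myh11 did the opposite. Pdgfra stood at 842 ± 276 CPM in Progenitor and 819 ± 64.2 in Intermediate, against 25.96 ± 1.95 in SMC1 and 7.195 ± 1.27 in SMC2. Acta2 (chromosome 19, 34241090 to 34255590 in GRCm38, the assembly that UCSC calls mm10) stood at 19480 ± 2247 CPM in SMC1 and 14510 ± 2391 in SMC2, against 203 ± 95.5 in Progenitor and 252 ± 43.2 in Intermediate. Pparg, the master regulator of adipocyte differentiation (chromosome 6, 115360951 to 115490399), was at 366 ± 77.6 CPM in SMC2, 27.9 ± 9.996 in Progenitor, 8.17 ± 3.75 in SMC1 and 2.27 ± 0.0504 in Intermediate. The adipocyte hormone gene Adipoq followed the same order of groups, with 90.2 ± 27.8 CPM in SMC2 and 4.38 ± 2.39 in Progenitor, 1.23 ± 0.745 in SMC1 and 0.483 ± 0.131 in Intermediate. Ucp1, which encodes the uncoupling protein of thermogenic fat, had a mean of 1.003 CPM in SMC2 and lower means elsewhere, near the limit of detection. The leukocyte marker Ptprc had means between 8.08 and 12.7 CPM. The smooth muscle gene Tagln was at only 49.5 ± 8.49 CPM in SMC1. Of its exon bases, 67.9% overlap another annotated gene, so its level is uncertain.

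**Figure D1:**
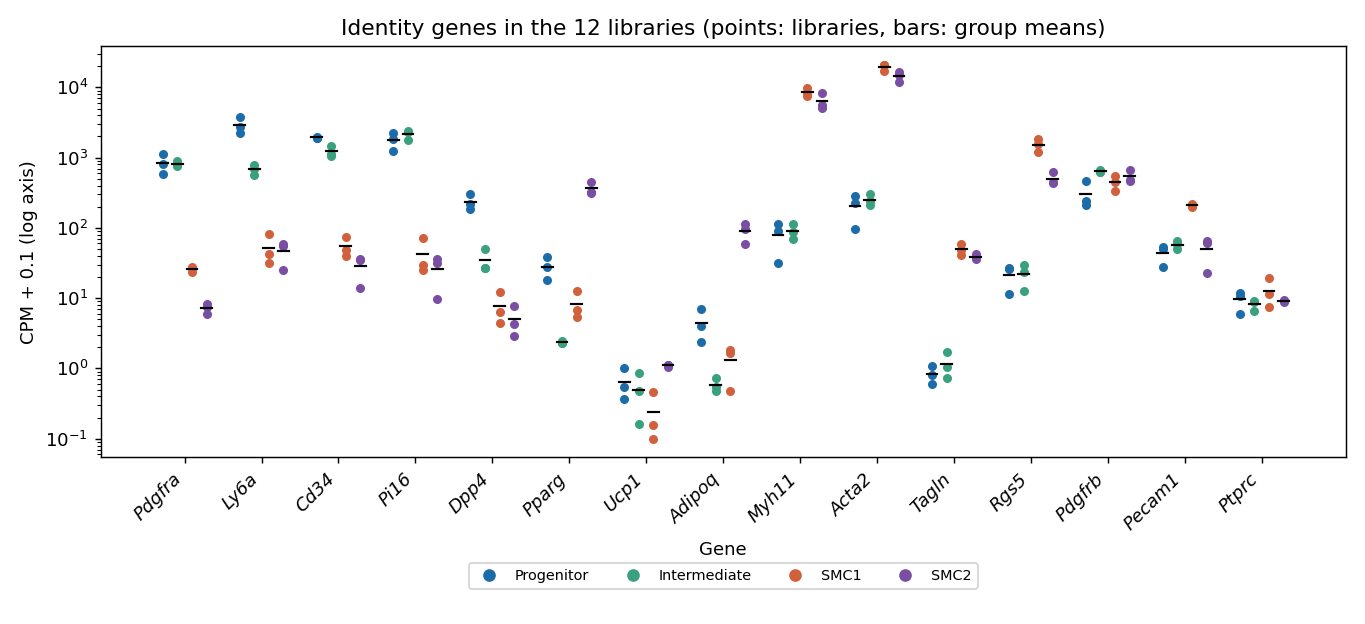
Levels of 15 identity genes in the 12 libraries, as CPM plus 0.1 on a log axis, with points for libraries, bars for the mean of the 3 libraries and a colour per group. Acta2 and Myh11 are higher in every SMC1 and SMC2 library than in every Progenitor and Intermediate library, and Pparg and Adipoq are highest in the 3 SMC2 libraries.

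The groups were further apart than their replicates. Pearson correlations of log2 CPM across genes were 0.968 to 0.983 within groups, 0.942 to 0.955 between Progenitor and Intermediate, 0.913 to 0.933 between SMC1 and SMC2, and 0.85 to 0.876 between Progenitor and SMC1. Component 1 of a principal component analysis (53.2% of the variance) separated Progenitor and Intermediate from the SMC populations. Component 2 (20.8%) had SMC1 and Intermediate libraries on one side of 0 and SMC2 and Progenitor libraries on the other.

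**Figure D2:**
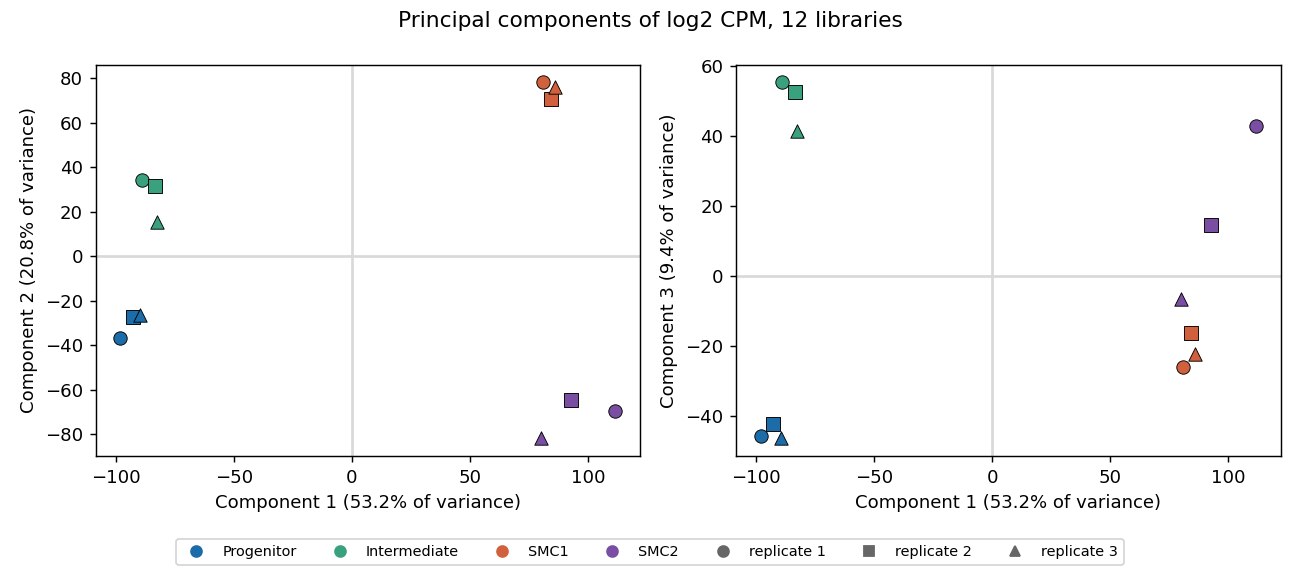
Principal components 1 to 3 of log2 CPM over 19016 genes, with a colour per group and a marker per replicate number. Component 1 holds 53.2% of the variance, component 2 20.8% and component 3 9.4%, and each group's 3 libraries lie together, with SMC2 the most spread on component 3.

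Between Intermediate and Progenitor, most called members of the progenitor, preadipocyte and chemokine lists were lower in Intermediate and most of the elastic fibre and vascular tone lists higher, while Acta2 and Myh11 were not called. None of these 5 list calls held with an estimated correlation, where adjusted p ran from 0.449 to 0.824, and the elastic fibre list had adjusted p = 0.0543 with the replicate number as a block. Of 19016 genes tested, 4218 were called, 2419 higher and 1799 lower in Intermediate, and 971 and 1029 of these changed at least 2-fold. These counts come from the fit without a block. With the replicate number as a block, 4594 genes were called, 2583 higher and 2011 lower. Fmod, which encodes the collagen-binding proteoglycan fibromodulin (chromosome 1, 134037254 to 134048277), was higher at 2157 ± 522 CPM against 81.1 ± 33.1, a log2 change of 4.73 ± 0.35 (adjusted p = 6.10e-08). Sult1e1, the oestrogen sulfotransferase (chromosome 5, 87575969 to 87591594), fell from 530.2 ± 137 CPM in Progenitor to 1.09 ± 0.199 in Intermediate, a log2 change of -8.92 ± 0.44 (adjusted p = 1.41e-09). All genes named by rank of fold change, here and below, had no overlap between the 3 libraries of each group, which chance gives for 10% of genes.

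Other genes among those with the highest log2 change in Intermediate over Progenitor were the proteoglycan gene Esm1 (4.93), the BMP family ligand Gdf6 (4.34), the Hedgehog inhibitor Hhip (4.25), the cadherin Cdh12 (4.0), Pex5l (3.97), Shisa2 (3.82), the secreted Wnt antagonist Frzb (3.82) and Angptl7 (3.78). Those with the lowest were the immunoglobulin genes Jchain (-6.78) and Igkc (-6.01), the phospholipase gene Pla1a (-6.64), the growth factor gene Fgf10 (-6.57), the chemokine Cxcl14 (-6.01), haptoglobin (Hp, -5.91), the decoy interleukin receptor Il1r2 (-5.54), Gpr165 (-5.14) and vitronectin (Vtn, -5.1). Jchain and Igkc are transcripts of antibody-producing plasma cells.

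In the interstitial fibroblast progenitor list, 0 of 20 tested members were higher and 14 lower, with 6 not called (0 higher and 15 lower adjusted over the list alone), among them Tnfaip6 (-2.65), Efhd1 (-2.87), Bmp7 (-3.79) and Ly6c1 (-2.97). Its camera adjusted p = 5.71e-14, and adjusted p = 0.449 with an estimated correlation. Ly6a (-2.09) and the peptidase gene Dpp4 (-2.77) were lower in Intermediate, whereas Pdgfra (-0.04), Cd34 (-0.65) and Pi16 (0.27) were not called. In the committed preadipocyte list, 3 of 18 tested members were higher and 10 lower, with 5 not called (3 higher and 11 lower adjusted over the list alone). The committed preadipocyte list had a camera adjusted p = 2.66e-08, and adjusted p = 0.455 with an estimated correlation. Pparg (-3.62), the lipoprotein lipase gene Lpl (-3.25) and Ggt5 (-2.06) fell. In the complement and chemokine list, 2 of 20 tested members were higher and 11 lower, with 7 not called (3 higher and 12 lower adjusted over the list alone). The complement and chemokine list had a camera adjusted p = 1.16e-05, and adjusted p = 0.488 with an estimated correlation. Ccl11 (-4.5), Ccl2 (-2.28), Il1r1 (-1.35) and Il6 (-1.57) were lower in Intermediate.

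In the vascular tone signalling list, 10 of 22 tested members were higher and 2 lower, with 10 not called (12 higher and 3 lower adjusted over the list alone). The vascular tone signalling list had a camera adjusted p = 1.63e-04, and adjusted p = 0.488 with an estimated correlation. The calcium-activated potassium channel gene Kcnma1 (2.5) and the guanylate cyclase subunit Gucy1a1 (1.64) rose, and the adrenergic receptor gene Adra1b fell (-3.69). In the elastic fibre list, 7 of 13 tested members were higher and 2 lower, with 4 not called (8 higher and 3 lower adjusted over the list alone). The elastic fibre list had a camera adjusted p = 0.0321, and adjusted p = 0.824 with an estimated correlation, and adjusted p = 0.0543 with the replicate number as a block. Without Intermediate replicate 1 this list's adjusted p was 0.0949, and without Progenitor replicate 1 it was 0.0569. Elastin (Eln) rose by 2.88 ± 0.31, its crosslinking enzyme Lox by 1.33 and Ltbp1 by 1.2, while Efemp1 fell (-2.05). In the contractile smooth muscle list, 6 of 26 tested members were higher and 2 lower, with 18 not called (6 higher and 2 lower adjusted over the list alone). The contractile smooth muscle list had a camera adjusted p = 0.357. The cytoskeletal genes Smtn (0.96) and Mylk (0.85) were higher and desmin (Des, -1.93) lower, and Mylk had adjusted p = 0.0542 in edgeR's test without Progenitor replicate 1. In the oxidative phosphorylation list, 0 of 28 tested members were higher and 9 lower, with 19 not called (0 higher and 10 lower adjusted over the list alone). The oxidative phosphorylation list had a camera adjusted p = 0.00307, and adjusted p = 0.824 with an estimated correlation. Mitochondrial genes took 0.542 ± 0.00235% of counts in Intermediate and 1.17 ± 0.2995% in Progenitor (SD, n = 3).

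In the mesothelial list, fixed as a marker of another cell type, 13 of 16 tested members were higher and 1 lower, with 2 not called (13 higher and 1 lower adjusted over the list alone). The mesothelial list had a camera adjusted p = 3.27e-06, and adjusted p = 0.615 with an estimated correlation. The keratin gene Krt8 stood at 11.6 ± 9.14 CPM in Intermediate against 0.829 ± 0.149 in Progenitor, and the uroplakin genes Upk1b (3.55) and Upk3b (2.58) rose as well. Most called members of the elastic fibre and vascular tone lists were also higher in Intermediate. Whether they moved with the mesothelial members across libraries was not tested. The call count was 2771 without Intermediate replicate 2, and higher calls made up 57.3% of all calls with TMM scaling but 49.8% with median-of-ratios and 39.2% with upper-quartile factors.

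Between SMC1 and Progenitor, all 26 tested members of the contractile smooth muscle list were higher in SMC1, and all 20 tested members of the complement and chemokine list were lower. In total 9194 of 19016 genes were called, 4804 higher and 4390 lower in SMC1, of which 2585 and 3220 changed at least 2-fold. Myh11, the smooth muscle myosin heavy chain, stood at 8457 ± 1071 CPM in SMC1 and 79.3 ± 42.6 in Progenitor, a log2 change of 6.74 ± 0.43 (adjusted p = 5.07e-10). The chemokine gene Ccl11 went the other way, with 5.22 ± 2.68 CPM in SMC1 and 900.2 ± 335 in Progenitor, a log2 change of -7.42 ± 0.45 (adjusted p = 1.22e-09).

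The genes with the highest log2 change in SMC1 over Progenitor, besides Myh11, were the potassium channel gene Kcnh2 (7.21), Susd5 (7.0), the smooth muscle transcriptional coactivator Myocd (6.97), the matrix protein gene Npnt (6.83), sclerostin (Sost, 6.78), Xirp1 (6.77), the cation transporter Slc22a3 (6.75), Itih4 (6.71) and Ldb3 (6.67). Those with the lowest, besides Ccl11, were Sult1e1 (-8.51), Epyc (-8.43), Cxcl14 (-7.81), the lipocalin gene Apod (-7.7), Cxcl13 (-7.61), the methyltransferase gene Inmt (-7.47) and the related interferon-inducible genes Ifi205 (-8.0), Ifi204 (-7.27) and Ifi202b (-7.22). The last 3 belong to a family of related neighbouring genes whose reads can be split between copies, and Epyc overlaps another annotated gene over part of its exons, so these values are uncertain.

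The contractile list had a camera adjusted p = 1.31e-48, and adjusted p = 0.0116 with an estimated correlation, and its examples Tpm2 (6.07), Synpo2 (5.68) and Pcp4l1 (5.49) rose. The complement and chemokine list had a camera adjusted p = 2.40e-28, and adjusted p = 0.0116 with an estimated correlation, with C1s1 (-3.54), C1ra (-3.65), Il33 (-4.76) and Ccl2 (-5.59) lower. Adjusted over the list alone, the 26 and 20 calls were the same in number. In the vascular tone signalling list, 17 of 22 tested members were higher and 3 lower, with 2 not called (17 higher and 4 lower adjusted over the list alone). The vascular tone signalling list had a camera adjusted p = 2.80e-11, and adjusted p = 0.083 with an estimated correlation. Kcnma1 (5.14) and the guanylate cyclase subunits Gucy1b1 (4.87) and Gucy1a1 (4.75) rose, while the vasopressin receptor gene Avpr1a fell (-5.94). In the pericyte list, 10 of 15 tested members were higher and 4 lower, with 1 not called (11 higher and 4 lower adjusted over the list alone). The pericyte list had a camera adjusted p = 0.0384, and adjusted p = 0.251 with an estimated correlation, and adjusted p = 0.0785 without Progenitor replicate 2; Mcam (6.32) and Cspg4 (5.46) rose and Steap4 fell (-6.19).

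In the interstitial fibroblast progenitor list, 3 of 20 tested members were higher and 16 lower, with 1 not called (3 higher and 16 lower adjusted over the list alone). The interstitial fibroblast progenitor list had a camera adjusted p = 1.08e-08, and adjusted p = 0.191 with an estimated correlation. Pdgfra (-5.02), Opcml (-6.06) and Tnfaip6 (-5.24) fell and Limch1 rose (3.78). In the committed preadipocyte list, 2 of 18 tested members were higher and 13 lower, with 3 not called (2 higher and 13 lower adjusted over the list alone). The committed preadipocyte list had a camera adjusted p = 7.33e-12, and adjusted p = 0.0564 with an estimated correlation. Gpc3 (-4.62) and Vit (-4.44) fell. In the interstitial matrix list, 3 of 24 tested members were higher and 17 lower, with 4 not called (3 higher and 18 lower adjusted over the list alone). The interstitial matrix list had a camera adjusted p = 3.25e-06, and adjusted p = 0.418 with an estimated correlation. Col5a3 (-5.27), Pcolce (-4.76), Clec3b (-6.37) and Fbln1 (-4.77) fell. In the matrix protease and inhibitor list, 5 of 20 tested members were higher and 12 lower, with 3 not called (5 higher and 12 lower adjusted over the list alone). The matrix protease and inhibitor list had a camera adjusted p = 1.91e-04, and adjusted p = 0.234 with an estimated correlation. The cathepsin gene Ctsk fell (-4.29) and the inhibitor Timp4 rose (4.44). In the interferon response list, 0 of 24 tested members were higher and 20 lower, with 4 not called (0 higher and 20 lower adjusted over the list alone). The interferon response list had a camera adjusted p = 1.12e-07, and adjusted p = 0.1 with an estimated correlation. Ifitm3 (-2.57) and Rtp4 (-3.27) fell. Higher calls made up 52.3% of all calls with TMM scaling, 49.3% with median-of-ratios and 41.3% with upper-quartile factors.

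**Figure D3:**
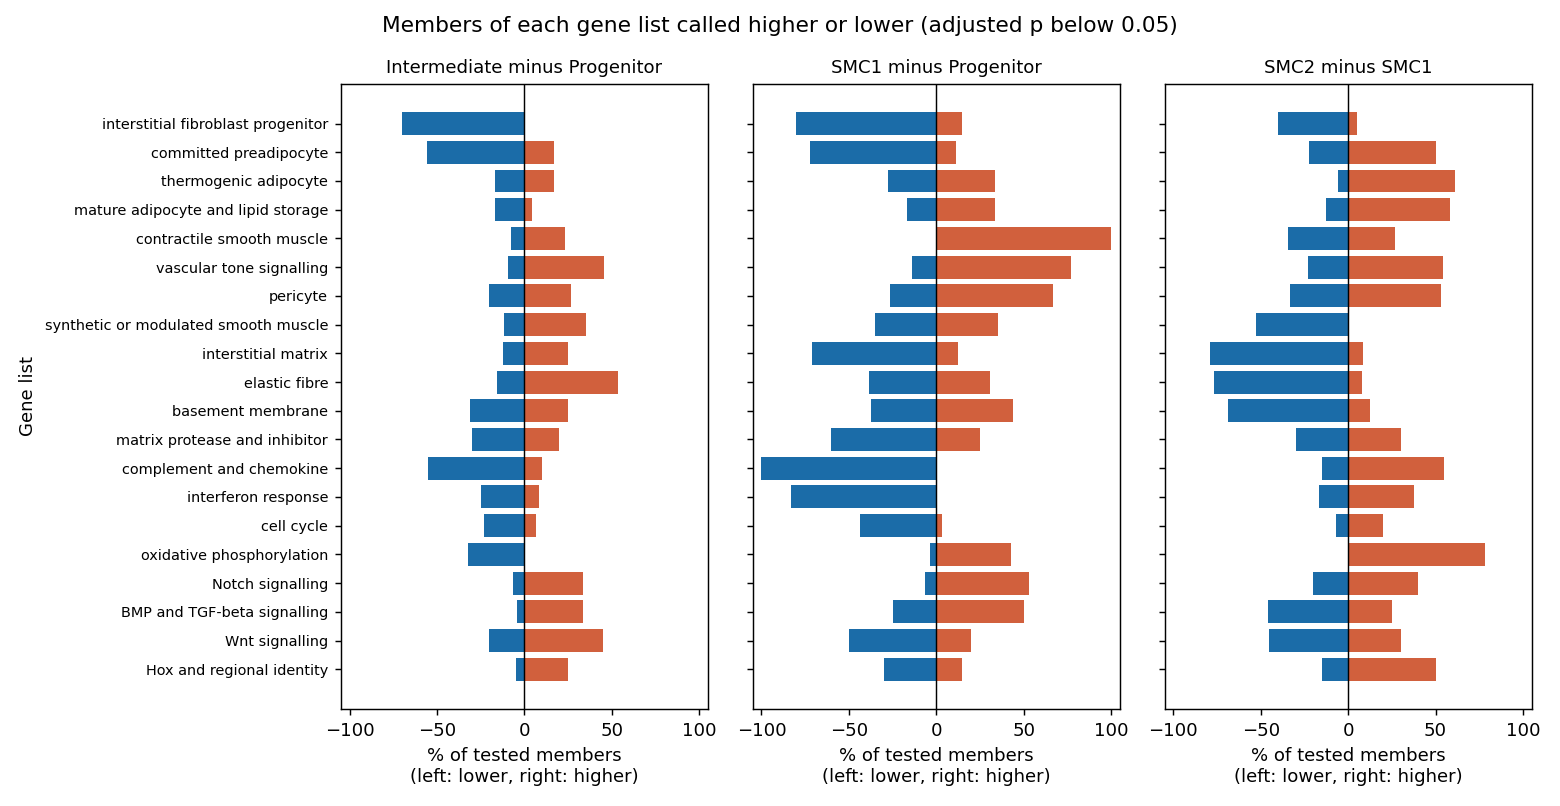
Percent of the tested members of each of 20 gene lists that were called higher (right) or lower (left) in the 3 main comparisons at an adjusted p below 0.05 in edgeR's test. In SMC1 minus Progenitor all 26 contractile members lie to the right and all 20 complement and chemokine members to the left, and in SMC2 minus SMC1 the interstitial matrix, elastic fibre and basement membrane lists lie mostly to the left and oxidative phosphorylation to the right.

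Between SMC2 and SMC1, most called members of the adipocyte, vascular tone and oxidative phosphorylation lists were higher in SMC2 and most of the interstitial matrix list lower. With an estimated correlation the thermogenic list kept its call at adjusted p = 0.0492, but adjusted p was 0.0623 for the mature adipocyte, 0.278 for the vascular tone and interstitial matrix and 0.347 for the oxidative phosphorylation lists. No call was made for Acta2 (-0.43 ± 0.29) or Myh11 (-0.41 ± 0.34). In total 6578 of 19016 genes were called, 3139 higher and 3439 lower in SMC2, of which 2305 and 1741 changed at least 2-fold. The balance turned with upper-quartile factors, to 3729 higher and 2843 lower. The transcription factor gene Tbx5 (chromosome 5, 119832668 to 119885219) stood at 101 ± 30.9 CPM in SMC2 and 0.382 ± 0.165 in SMC1, a log2 change of 8.03 ± 0.33 (adjusted p = 9.83e-13). Pparg was higher by 5.48 ± 0.32 (adjusted p = 8.64e-10), and elastin (Eln, chromosome 5, 134702593 to 134747323) was at 529 ± 188 CPM against 4651 ± 825 in SMC1, a log2 change of -3.14 ± 0.32 (adjusted p = 2.60e-07).

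The other genes with the highest log2 change in SMC2 over SMC1 were the olfactory receptor genes Olfr78 (7.54) and Olfr558 (7.21), the paraoxonase gene Pon1 (7.23), the cGMP-dependent kinase Prkg2 (7.12), the prostaglandin receptor Ptger2 (7.06), Rergl (7.01), the secretin receptor Sctr (7.0), the capsaicin receptor channel Trpv1 (6.95) and the cytochrome P450 gene Cyp2e1 (6.85). Those with the lowest were the angiotensin-converting enzyme gene Ace (-3.74), Galnt15 (-3.7), Sytl5 (-3.69), the myosin kinase gene Mylk4 (-3.57), Lratd1 (-3.55), fibronectin (Fn1, -3.51), Col15a1 (-3.5), osteoprotegerin (Tnfrsf11b, -3.5), Lars2 (-3.46) and Fgf14 (-3.44). Lars2 had adjusted p = 0.0237 in edgeR's test, and 0.0607 without SMC1 replicate 1, 0.0576 without SMC1 replicate 3, and 0.0688, 0.0842 and 0.0772 without SMC2 replicates 1, 2 and 3.

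In the mature adipocyte and lipid storage list, 14 of 24 tested members were higher and 3 lower, with 7 not called (14 higher and 3 lower adjusted over the list alone). The mature adipocyte and lipid storage list had a camera adjusted p = 7.17e-09, and adjusted p = 0.0623 with an estimated correlation. The lipid droplet gene Plin1 (6.73 ± 0.35), the gluconeogenic and glyceroneogenic enzyme gene Pck1 (5.91), the glucose transporter Slc2a4 (3.42), the triglyceride lipase Pnpla2 (2.86) and Adipoq (6.22 ± 0.46) rose. Bulk RNA of sorted cells did not separate transcripts of the SMC2 cells from adipocyte RNA in the sort. In the thermogenic adipocyte list, 11 of 18 tested members were higher and 1 lower, with 6 not called (12 higher and 2 lower adjusted over the list alone). The thermogenic adipocyte list had a camera adjusted p = 9.48e-06, and adjusted p = 0.0492 with an estimated correlation. Ebf2 (4.55), Kcnk3 (3.93), the mitochondrial biogenesis coactivator Ppargc1a (2.02) and Cox7a1 (3.11) rose. Ucp1 had 59 raw counts in the 3 SMC2 libraries and 8 in SMC1, with adjusted p = 0.0161 in edgeR's test, and 0.0671 and 0.0635 without SMC1 replicates 2 and 3. In the committed preadipocyte list, 9 of 18 tested members were higher and 4 lower, with 5 not called (9 higher and 4 lower adjusted over the list alone). The committed preadipocyte list had a camera adjusted p = 0.00505, and adjusted p = 0.347 with an estimated correlation. Lpl (4.88) and Fabp4 (2.92) rose and Fmo2 fell (-2.75). In the oxidative phosphorylation list, 22 of 28 tested members were higher and 0 lower, with 6 not called (25 higher and 0 lower adjusted over the list alone). The oxidative phosphorylation list had a camera adjusted p = 4.04e-07, and adjusted p = 0.347 with an estimated correlation. Cycs (1.82) rose.

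In the vascular tone signalling list, 12 of 22 tested members were higher and 5 lower, with 5 not called (13 higher and 5 lower adjusted over the list alone). The vascular tone signalling list had a camera adjusted p = 8.27e-06, and adjusted p = 0.278 with an estimated correlation. The cation channel gene Trpc6 (4.58), the angiotensin receptor gene Agtr1a (4.86), the endothelin receptor gene Ednra (3.22) and Rgs4 (3.75) rose. In the pericyte list, 8 of 15 tested members were higher and 5 lower, with 2 not called (8 higher and 5 lower adjusted over the list alone). The pericyte list had a camera adjusted p = 2.28e-06, and adjusted p = 0.052 with an estimated correlation. Higd1b (5.35), Ndufa4l2 (5.75) and Cox4i2 (3.55) rose and Rgs5 fell (-1.6). In the contractile smooth muscle list, 7 of 26 tested members were higher and 9 lower, with 10 not called (7 higher and 12 lower adjusted over the list alone). The contractile smooth muscle list had a camera adjusted p = 0.724. Its median log2 change was -0.42, its mean was 0 and camera gave the direction as up, and its examples Casq2 (6.0) and Pcp4l1 (3.3) rose while the integrin gene Itga8 fell (-3.18).

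In the interstitial matrix list, 2 of 24 tested members were higher and 19 lower, with 3 not called (2 higher and 20 lower adjusted over the list alone). The interstitial matrix list had a camera adjusted p = 6.67e-13, and adjusted p = 0.278 with an estimated correlation. Col5a2 (-2.61), Fbn1 (-3.11), Col5a1 (-2.79) and Col3a1 (-2.58) fell. In the elastic fibre list, 1 of 13 tested members were higher and 10 lower, with 2 not called (1 higher and 10 lower adjusted over the list alone). The elastic fibre list had a camera adjusted p = 8.51e-08, and adjusted p = 0.278 with an estimated correlation. Ltbp1 (-2.65) and Emilin1 (-2.14) fell. In the basement membrane list, 2 of 16 tested members were higher and 11 lower, with 3 not called (3 higher and 12 lower adjusted over the list alone). The basement membrane list had a camera adjusted p = 1.82e-06, and adjusted p = 0.347 with an estimated correlation. Lamc3 (-2.84) and Col4a5 (-2.45) fell. In the list of synthetic or modulated smooth muscle, 0 of 17 tested members were higher and 9 lower, with 8 not called (0 higher and 9 lower adjusted over the list alone). The synthetic or modulated smooth muscle list had a camera adjusted p = 2.97e-05, and adjusted p = 0.278 with an estimated correlation. The calcification inhibitor Mgp (-2.94) and Ibsp (-2.36) fell. Of 20 interstitial fibroblast progenitor members, 1 was higher and 8 lower, with 11 not called (camera adjusted p = 9.91e-04, and 0.347 with an estimated correlation). Pdgfra stood at 7.195 ± 1.27 CPM in SMC2 and 25.96 ± 1.95 in SMC1. Of 20 complement and chemokine members, 11 were higher and 3 lower, with 6 not called (camera adjusted p = 0.00104, and 0.347 with an estimated correlation).

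Markers of other cell types also differed between SMC2 and SMC1. In the endothelial list, 2 of 20 tested members were higher and 10 lower, with 8 not called (2 higher and 12 lower adjusted over the list alone). The endothelial list had a camera adjusted p = 0.00827, and adjusted p = 0.623 with an estimated correlation. Pecam1 stood at 209 ± 8.62 CPM in SMC1 and 49.8 ± 23.3 in SMC2. In the Schwann cell list, 8 of 14 tested members were higher and 1 lower, with 5 not called (8 higher and 2 lower adjusted over the list alone). The Schwann cell list had a camera adjusted p = 0.0234, and adjusted p = 0.492 with an estimated correlation. Without SMC1 replicate 2 its camera adjusted p was 0.0725. Gfra3 (4.37) was higher in SMC2. In the skeletal muscle list, 6 of 11 tested members were higher and 0 lower, with 5 not called (7 higher and 0 lower adjusted over the list alone). The skeletal muscle list had a camera adjusted p = 0.00752, and adjusted p = 0.347 with an estimated correlation. Mybpc1 (5.95) and Acta1 (2.22) rose. In the dissociation stress list, which reports on sample handling, 13 of 24 tested members were higher and 4 lower, with 7 not called (13 higher and 4 lower adjusted over the list alone). The dissociation stress list had a camera adjusted p = 0.00281, and adjusted p = 0.347 with an estimated correlation. Myc (2.54) and Nr4a1 (2.0) rose. Mitochondrial genes took 1.67 ± 0.183% of counts in SMC2, 1.2 ± 0.214% in SMC1, 1.17 ± 0.2995% in Progenitor and 0.542 ± 0.00235% in Intermediate.

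In SMC2 against Progenitor, the olfactory receptor genes Olfr78 (10.29 ± 0.57) and Olfr558 (10.13 ± 0.33), Myl1 (9.63 ± 0.45) and Rergl (9.59 ± 0.33) led the higher genes. Ifi205 (-7.5), Cxcl14 (-7.14), the BMP regulator Bmper (-7.07) and Inmt (-6.98) led the lower. Of 8522 genes called, 4394 were higher and 4128 lower. The balance turned to 4089 higher and 4511 lower with upper-quartile factors and to 4237 and 4257 with median-of-ratios factors. Myl1, a muscle myosin light chain, stood at 50.7 ± 11.5 CPM in SMC2, and all Progenitor libraries together held 3 of its reads. In the mature adipocyte list, 16 of 24 tested members were higher and 1 lower, with 7 not called (17 higher and 1 lower adjusted over the list alone). The mature adipocyte and lipid storage list had a camera adjusted p = 1.31e-10, and adjusted p = 0.0271 with an estimated correlation. In the thermogenic list, 11 of 18 tested members were higher and 3 lower, with 4 not called (11 higher and 3 lower adjusted over the list alone). The thermogenic adipocyte list had a camera adjusted p = 2.19e-04, and adjusted p = 0.0271 with an estimated correlation. Pparg (3.71) and Adipoq (4.33) were higher in SMC2 and Ucp1 (0.85) was not called. In the interstitial fibroblast progenitor list, 1 of 20 tested members were higher and 17 lower, with 2 not called (2 higher and 17 lower adjusted over the list alone). The interstitial fibroblast progenitor list had a camera adjusted p = 6.04e-15, and adjusted p = 0.0271 with an estimated correlation. The smallest camera adjusted p belonged to other lists. All 26 tested contractile members were higher (3.64e-50, and 0.0256 with an estimated correlation). Of 22 vascular tone members, 20 were higher and 2 lower (7.71e-22 and 0.0271). Of 24 interstitial matrix members, 0 were higher and 23 lower (9.26e-22 and 0.04865). Of 20 complement and chemokine members, 0 were higher and 19 lower (2.64e-19 and 0.0271). Some lists of other cell types and of handling were higher in SMC2 as well. In the Schwann cell list, 11 of 14 tested members were higher and 1 lower, with 2 not called (11 higher and 1 lower adjusted over the list alone). The Schwann cell list had a camera adjusted p = 4.89e-05, and adjusted p = 0.205 with an estimated correlation. In the cardiac muscle list, 4 of 8 tested members were higher and 0 lower, with 4 not called (4 higher and 0 lower adjusted over the list alone). The cardiac muscle list had a camera adjusted p = 0.00207, and adjusted p = 0.0811 with an estimated correlation. In the dissociation stress list, 13 of 24 tested members were higher and 2 lower, with 9 not called (14 higher and 2 lower adjusted over the list alone), with a camera adjusted p = 0.0112, and adjusted p = 0.407 with an estimated correlation.

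In SMC1 against Intermediate, Sost (7.14 ± 0.47), the serotonin receptor gene Htr1b (7.09 ± 0.58), Xirp1 (6.85) and Myoz2 (6.79) led the higher genes, and Angptl7 (-7.3 ± 0.48), Fmod (-6.8), the steroid enzyme gene Hsd11b1 (-6.78) and Shisa3 (-6.65) the lower. Of 7908 genes called, 3753 were higher and 4155 lower. In the contractile list, 26 of 26 tested members were higher and 0 lower, with 0 not called (26 higher and 0 lower adjusted over the list alone). The contractile smooth muscle list had a camera adjusted p = 8.80e-57, and adjusted p = 0.019 with an estimated correlation. In the complement and chemokine list, 0 of 20 tested members were higher and 19 lower, with 1 not called (0 higher and 19 lower adjusted over the list alone). The complement and chemokine list had a camera adjusted p = 5.84e-24, and adjusted p = 0.019 with an estimated correlation. Lists of other cell types moved as well. In the mesothelial list, 0 of 16 tested members were higher and 14 lower, with 2 not called (0 higher and 14 lower adjusted over the list alone). The mesothelial list had a camera adjusted p = 8.76e-05, and adjusted p = 0.443 with an estimated correlation. In the endothelial list, 14 of 20 tested members were higher and 1 lower, with 5 not called (16 higher and 1 lower adjusted over the list alone). The endothelial list had a camera adjusted p = 0.0052, and adjusted p = 0.631 with an estimated correlation. In the Schwann cell list, 9 of 14 tested members were higher and 1 lower, with 4 not called (10 higher and 1 lower adjusted over the list alone). The Schwann cell list had a camera adjusted p = 0.00142, and adjusted p = 0.338 with an estimated correlation. In the cardiac muscle list, 5 of 8 tested members were higher and 1 lower, with 2 not called (5 higher and 1 lower adjusted over the list alone), with a camera adjusted p = 0.0155, and adjusted p = 0.258 with an estimated correlation.

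In SMC2 against Intermediate, Rergl (11.07 ± 0.37) and Olfr78 (10.32 ± 0.57) led the higher genes, and Hhip (-8.18 ± 0.38), Angptl7 (-7.89), the stromelysin gene Mmp3 (-7.54) and the complement gene C7 (-7.29) the lower. Of 8481 genes called, 4078 were higher and 4403 lower, a balance that turned to 4662 higher and 4027 lower with upper-quartile factors and to 4271 and 4261 with median-of-ratios factors. Myl1 had 2 reads and Sbspon 3 reads in the Intermediate libraries together, against 50.7 and 62.9 CPM in SMC2, and 0.728 of the exon bases of Sbspon overlap another annotated gene. In the contractile list, 26 of 26 tested members were higher and 0 lower, with 0 not called (26 higher and 0 lower adjusted over the list alone). The contractile smooth muscle list had a camera adjusted p = 1.46e-47, and adjusted p = 0.0439 with an estimated correlation. In the oxidative phosphorylation list, 27 of 28 tested members were higher and 0 lower, with 1 not called (27 higher and 0 lower adjusted over the list alone). The oxidative phosphorylation list had a camera adjusted p = 7.75e-12, and adjusted p = 0.174 with an estimated correlation. Among other cell types, in the mesothelial list, 0 of 16 tested members were higher and 15 lower, with 1 not called (1 higher and 15 lower adjusted over the list alone). The mesothelial list had a camera adjusted p = 4.24e-05, and adjusted p = 0.32 with an estimated correlation. In the Schwann cell list, 10 of 14 tested members were higher and 1 lower, with 3 not called (11 higher and 1 lower adjusted over the list alone). The Schwann cell list had a camera adjusted p = 3.09e-05, and adjusted p = 0.187 with an estimated correlation. In the cardiac muscle list, 3 of 8 tested members were higher and 0 lower, with 5 not called (3 higher and 0 lower adjusted over the list alone). The cardiac muscle list had a camera adjusted p = 0.00143, and adjusted p = 0.111 with an estimated correlation. In the skeletal muscle list, 6 of 11 tested members were higher and 0 lower, with 5 not called (6 higher and 0 lower adjusted over the list alone). The skeletal muscle list had a camera adjusted p = 0.0317, and adjusted p = 0.32 with an estimated correlation, and adjusted p = 0.0645 without Intermediate replicate 1 and 0.0537 without SMC2 replicate 3.

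Because the labels call the sorted cells intermediate, each library was placed on a line from the Progenitor mean (0) to the SMC1 mean (1) over the 5805 genes that differed at least 2-fold between those groups. Intermediate libraries lay at 0.21 ± 0.013, Progenitor libraries at 0.014 ± 0.05, SMC1 libraries at 0.985 ± 0.034 and SMC2 libraries at 0.73 ± 0.06 (SD, n = 3). Over the axis genes lower in SMC1, Intermediate lay at 0.241 ± 0.019, and over those higher in SMC1 at 0.171 ± 0.029, a division chosen after the data were seen. On an axis that ended at SMC2, Intermediate lay at 0.115 ± 0.023. No test was made of these positions. The slope does not measure how far a library lies off the line. On component 1, Intermediate libraries lay from -89 to -82.8, Progenitor from -98.1 to -89.7 and SMC1 from 80.9 to 86.1. On component 2 these ranges were 15.6 to 34.4, -36.8 to -26.2 and 70.6 to 78.2. On component 3 they were 41.3 to 55.2, -46.5 to -42.3 and -26 to -16.5, so Intermediate lay outside the other 2 groups there.

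**Figure D4:**
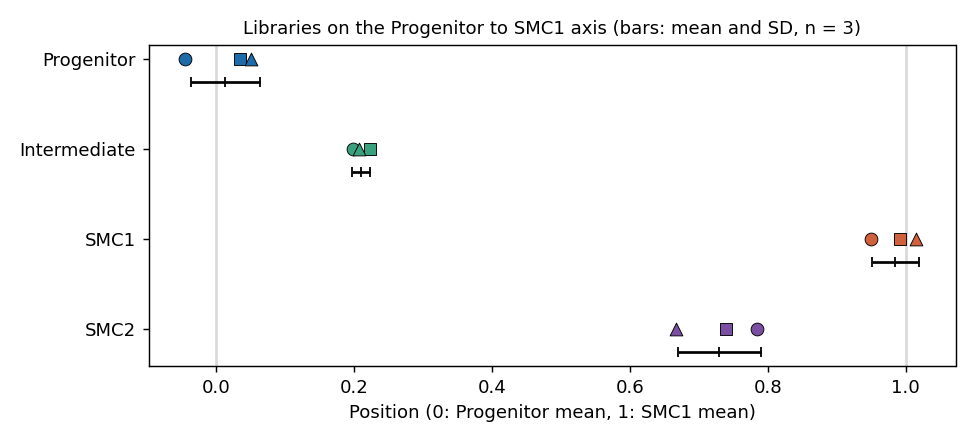
Position of each of the 12 libraries on the axis from the Progenitor mean (0) to the SMC1 mean (1), with a marker per replicate number and bars for the mean and SD of each group (n = 3). The 3 Intermediate libraries lie between 0.199 and 0.224, above the highest Progenitor library at 0.051 and below the lowest SMC2 library at 0.667.

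In SMC1 minus Progenitor, some lists of other cell types differed as well. In the endothelial list, 13 of 20 tested members were higher and 2 lower, with 5 not called (15 higher and 2 lower adjusted over the list alone). The endothelial list had a camera adjusted p = 0.0323, and adjusted p = 0.807 with an estimated correlation, and adjusted p = 0.0577 without Progenitor replicate 1 and 0.0566 without SMC1 replicate 1. Pecam1 stood at 209 ± 8.62 CPM in SMC1 and 43.5 ± 14.2 in Progenitor (adjusted p = 1.77e-05 in edgeR's quasi-likelihood test). In the Schwann cell list, 8 of 14 tested members were higher and 1 lower, with 5 not called (8 higher and 1 lower adjusted over the list alone). The Schwann cell list had a camera adjusted p = 0.0111, and adjusted p = 0.5 with an estimated correlation. In the macrophage and myeloid list, 6 of 20 tested members were higher and 0 lower, with 14 not called (6 higher and 0 lower adjusted over the list alone). The macrophage and myeloid list had a camera adjusted p = 0.344. Without SMC1 replicate 1, edgeR's quasi-likelihood test gave adjusted p = 0.0991 for Itgam, 0.0721 for C1qa and 0.122 for Adgre1, so 3 of these calls were lost. The log2 changes of these genes were then 1.38, 1.12 and 0.96. For Adgre1, adjusted p was also 0.061 without Progenitor replicate 1 and 0.0537 without Progenitor replicate 3. For lymphocyte genes in that comparison, 0 of 15 tested members were higher and 2 lower, with 13 not called (0 higher and 1 lower adjusted over the list alone). The lymphocyte list had a camera adjusted p = 0.85. For erythroid genes, 0 of 5 tested members were higher and 0 lower, with 5 not called (0 higher and 0 lower adjusted over the list alone). The erythroid list had a camera adjusted p = 0.986. In the cardiac muscle list, 5 of 8 tested members were higher and 0 lower, with 3 not called (5 higher and 1 lower adjusted over the list alone). The cardiac muscle list had a camera adjusted p = 0.0466, and adjusted p = 0.361 with an estimated correlation, and adjusted p = 0.0762 without Progenitor replicate 1 and 0.0596 with the replicate number as a block; Ryr2 (3.4) and Tnnt2 (2.64) were higher in SMC1.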

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

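Alternatives that remove list members, divide the axis genes or rescale the genes called in 2 comparisons, and lists retested without a library, were chosen after the data were seen; the others were planned. Removing list members only subtracts their own calls and tests nothing. Requiring a 2-fold change lowered the calls, by construction, to 2000 for Intermediate minus Progenitor, 4046 for SMC2 minus SMC1, 5805 for SMC1 minus Progenitor, 5495 for SMC2 minus Progenitor, 5060 for SMC1 minus Intermediate and 5626 for SMC2 minus Intermediate. Leaving out a library gave 2771 to 4105 calls for Intermediate minus Progenitor, with the lowest without Intermediate replicate 2, where fewer libraries were tested. The other ranges, 5439 to 6599 for SMC2 minus SMC1, 7868 to 8615 for SMC1 minus Progenitor, 7298 to 8376 for SMC2 minus Progenitor, 6636 to 7227 for SMC1 minus Intermediate and 7128 to 8210 for SMC2 minus Intermediate, stayed within 1.5 times the reported counts, as did the scaling, filter, test and block alternatives. Upper-quartile factors moved the median log2 change of all genes from 0.078 to -0.08 for Intermediate minus Progenitor, from -0.005 to -0.187 for SMC1 minus Progenitor and from -0.003 to 0.107 for SMC2 minus SMC1, so small changes depend on the scaling. With the replicate block the calls were 4594 for Intermediate minus Progenitor, 6945 for SMC2 minus SMC1, 9664 for SMC1 minus Progenitor, 8842 for SMC2 minus Progenitor, 8223 for SMC1 minus Intermediate and 8839 for SMC2 minus Intermediate. The same-number correlations ranged from -0.02 to 0.35 outside Intermediate minus Progenitor. Of 12 libraries, 11 matched best with a library of their own number, which goes with pairing across the populations, though the labels do not say what a number marks. Among the gene and list results tested under the block, it ended 2 gene calls and 5 list calls; for Intermediate minus Progenitor these were Fcer1g and the elastic fibre and interferon response lists, both lists at adjusted p = 0.0543. Of all 4218 genes called there, 45 were not called under the block. Over all alternatives 5523 results of genes from the naming rule kept direction and call, 104 lost the call and 0 reversed. Those genes were already called and picked by change, adjusted p or identity, and each counts under many settings, so the selection favours stability. Of all 4218 genes called for Intermediate minus Progenitor, 828 were not called with upper-quartile factors, 868 with no filter and 1497 without Intermediate replicate 2. Of 98 list calls, 84 were lost with an estimated correlation and 14 kept, while all 98 kept with median-of-ratios factors. The Intermediate position was 0.213 with median-of-ratios factors, 0.226 on the 500 genes with the largest change, 0.115 on an axis ending at SMC2, 0.241 over axis genes lower in SMC1, 0.171 over those higher in SMC1, and 0.199 to 0.232 without a library, of which Progenitor replicates 2 and 3 moved it most, to 0.228 and 0.232; the cause was not tested. Depth limits genes such as Ucp1 with few counts.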

Other observations

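The Intermediate to Progenitor and SMC2 to SMC1 comparisons share no library, and the genes called in both mostly moved in opposite directions, a relation examined after the data were seen. Of 1964 genes called in both, 1504 (76.6%) went in opposite directions. Genes higher in Intermediate and lower in SMC2 numbered 1042 where independent lists give 437, and genes lower in Intermediate and higher in SMC2 numbered 462 against 297. Genes higher in both numbered 295 against 399, and lower in both 165 against 325. The Pearson correlation of the log2 changes across 19016 genes, which are not independent replicates, was -0.28. With upper-quartile factors, also chosen after the data were seen, 1366 of 1800 genes (75.9%) went in opposite directions, 662 higher in Intermediate and lower in SMC2 against 238 for independent lists and 704 the reverse against 485. With median-of-ratios factors these were 1367 of 1801 (75.9%), 868 against 343 and 499 against 335. Eln (2.88 and -3.14), Tnfrsf11b (2.96 and -3.5), Lamc3 (2.37 and -2.84) and Dkk3 (2.04 and -2.78) were higher in Intermediate and lower in SMC2, and Pparg (-3.62 and 5.48), Lpl (-3.25 and 4.88), Il6 (-1.57 and 3.62) and Myc (-1.68 and 2.54) the reverse.

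Developmental signalling lists were called in some comparisons and not in others. In the Hox and regional identity list, in SMC2 minus SMC1, 10 of 20 tested members were higher and 3 lower, with 7 not called (10 higher and 4 lower adjusted over the list alone). The Hox and regional identity list had a camera adjusted p = 0.0174, and adjusted p = 0.347 with an estimated correlation. Hoxc5 (4.44) and Hoxc8 (4.17) led, and in the other 5 comparisons camera did not call this list (adjusted p from 0.0553 to 0.984). In the Wnt list, in SMC1 minus Progenitor, 4 of 20 tested members were higher and 10 lower, with 6 not called (5 higher and 11 lower adjusted over the list alone). The Wnt signalling list had a camera adjusted p = 0.00302, and adjusted p = 0.407 with an estimated correlation. Wnt11 (-5.37), Dkk2 (-5.56) and Sfrp1 (-4.8) fell. Camera also called the Wnt list lower in SMC2 minus Progenitor (adjusted p = 1.90e-05), SMC1 minus Intermediate (7.18e-05) and SMC2 minus Intermediate. With an estimated correlation these were 0.144, 0.258 and 0.14. Camera did not call the Wnt list in Intermediate minus Progenitor (adjusted p = 0.404) or SMC2 minus SMC1 (adjusted p = 0.122). In the Notch list, in SMC1 minus Progenitor, 8 of 15 tested members were higher and 1 lower, with 6 not called (8 higher and 1 lower adjusted over the list alone). The Notch signalling list had a camera adjusted p = 0.0323, and adjusted p = 0.418 with an estimated correlation, and adjusted p = 0.0528 without Progenitor replicate 1; the target genes Hey2 (3.37) and Heyl (2.96) rose. Camera also called the Notch list higher in SMC2 minus Progenitor (adjusted p = 0.00286) and SMC2 minus Intermediate. With an estimated correlation these were 0.205 and 0.39. Camera did not call the Notch list in Intermediate minus Progenitor (adjusted p = 0.0853), SMC2 minus SMC1 (0.345) or SMC1 minus Intermediate (0.187). In the BMP and TGF-beta list, in Intermediate minus Progenitor, 8 of 24 tested members were higher and 1 lower, with 15 not called (10 higher and 1 lower adjusted over the list alone). The BMP and TGF-beta signalling list had a camera adjusted p = 0.00413, and adjusted p = 0.488 with an estimated correlation. Bmp4 (2.39), Tgfb3 (1.49) and Bmpr1b (2.2) rose, and in the other 5 comparisons camera did not call this list (adjusted p from 0.196 to 0.969). In the cell cycle list, in SMC1 minus Progenitor, 1 of 30 tested members were higher and 13 lower, with 16 not called (1 higher and 13 lower adjusted over the list alone). The cell cycle list had a camera adjusted p = 0.0807, and camera called this list in none of the 6 comparisons.

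All tests of the patterns that follow were chosen after the results were seen, and rules for 2 kinds of test were revised after a first run. The first rule for carried-over cells excluded them when a list's shared movement lay below the 5th percentile, and the adipocyte value of 4.2 would have met it. A steady amount of carried-over RNA in each library also gives little shared movement, so exclusion was changed to need scatter between members at or above the 95th percentile. The first rule for SMC2 cells in Progenitor used the median share of SMC2 genes, and the measured 3.12% would have gone with that explanation. A second rule excluded SMC2 cells when over 10% of those genes stood below a bound, which the measured 18.2% met, but that rule was set with the values known and rested on the lowest genes. The rule now used needs over 50%, so the question stays open.

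Adipocyte list members were higher in SMC2 than in SMC1, Adipoq at 90.2 against 1.23 CPM. The median log2 change over all 24 members was 1.38 (quartiles 0.20 and 3.74), and free RNA of the suspension was not tested apart from this pattern. Adipocyte cells or their RNA in the SMC2 sort stay open: across the SMC2 libraries the 14 called members' shared movement was at the 4.2 percentile of 10000 random lists and their scatter at the 85.8 percentile, which decides nothing. For Pparg alone, its range against the other members was at the 53.7 percentile of 257 matched genes, so adipocyte RNA and expression by SMC2 cells cannot be told apart. By library, Pparg stood at 455.7, 328.7 and 314.9 CPM in SMC2 replicates 1, 2 and 3 and Adipoq at 59.68, 96.91 and 114.1, so the library highest in Pparg was lowest in Adipoq, which 2 genes in 3 libraries leave open. Expression of these genes by the sorted SMC2 cells, the biological explanation, is untested. Camera also called the mature adipocyte list higher in SMC1 minus Progenitor (8 higher, 4 lower, adjusted p = 0.0438) and SMC1 minus Intermediate (8 higher, 3 lower, 0.00165). With an estimated correlation the camera adjusted p was 0.5 and 0.305. For SMC1 minus Progenitor it was 0.0547 with the replicate number as a block and 0.102 without Progenitor replicate 2.

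Mesothelial list members were higher in Intermediate than in Progenitor. Scaling between the groups would move the list with all genes, but its median lay 2.22 log2 units above the median of all genes with upper-quartile factors. The 13 called members moved together across the Intermediate libraries, by -0.41, -0.38 and 0.79 log2 units from their mean. Their shared movement was at percentile 100 of 10000 random lists, after rounding. This is consistent with mesothelial cells or their RNA in the Intermediate sort, in an amount that may differ between libraries, with Krt8 at 11.6 CPM and Upk3b at 80.0 among the markers. A mesothelial-type program that varies between the libraries' cells would look alike and was not tested, and the sort markers were not given in the sources used here.

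Contractile transcripts stood in Progenitor at a median of 2.08% of their SMC1 level and 2.51% of their SMC2 level over 26 members, with Acta2 at 203 CPM. They moved together across the Progenitor libraries, by -0.55, 0.27 and 0.28 log2 units (percentile 100 of 10000 random lists), as smooth muscle cells or their RNA in the sort could produce. Whether SMC2 cells are a source stays open. Of 88 genes much higher in SMC2 than in SMC1 (log2 change of at least 4 and abundant in SMC2), 16 (18.2%) stood in Progenitor below 0.485% of their SMC2 level, while the contractile list's lower quartile was 1.46%. The other genes stood at or above 0.485%, and the median over the 88 genes was 3.12%. Among the 16 were Olfr78 at 0.075% and Rergl at 0.132%, with 23 and 22 reads in the Progenitor libraries together. Myh11 stood in Progenitor at 1.25% and Acta2 at 1.4% of their SMC2 level. If the source is carried-over smooth muscle material, folds of SMC genes over Progenitor are understated; low expression in Progenitor cells themselves was not tested.

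For each comparison the 6 libraries form 10 splits, too few for a share below 0.05. In fits of those 6 libraries with edgeR's quasi-likelihood test, 1 split, the real one, called as many genes, with 4137 for Intermediate minus Progenitor, 6394 for SMC2 minus SMC1, 8587 for SMC1 minus Progenitor, 8044 for SMC2 minus Progenitor, 7965 for SMC1 minus Intermediate and 8644 for SMC2 minus Intermediate. The highest of the other splits called 0 in each comparison, with at most 837, 434, 337, 353, 675 and 455 genes at an unadjusted p below 0.05 in the same order. Each other split mixes both populations within its groups, which widens the fitted spread. Its 0 calls were therefore likely beforehand and say little about chance. For Intermediate minus Progenitor, 4 splits part all pairs, and the 3 others of these called 0.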
